A study of Homo sapiens with 12 samples.

How the data were processed

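Total RNA of Huh7 cells, an established human hepatoma line, was taken after 24 h with recombinant human or mouse erythroferrone (ERFE) at 10 µg/ml or without it, and biotinylated cRNA was made with an Ambion MessageAmp kit for Illumina arrays, per the labels' protocols. RNA was extracted with an RNeasy kit, per the labels' protocols. The growth protocol also mentions HepG2 cells, which are in none of the 12 samples. Each of the 3 groups had 4 arrays, assigned to groups and replicate numbers by their titles. A pair of mouse ERFE arrays is titled replicate 3, and these are called 3-A4 and 3-B4 after the code that opens their titles, whose meaning is not given. Their difference had an SD of 0.262 on the log2 scale, the second smallest of all pairs within groups (0.259 to 0.384), which does not show whether they are separate samples. They were deposited as 2 samples with different codes and different values and were kept as 2, with their mean as an alternative. The submitters name 4 replicates per condition, which the mouse ERFE group reaches only with both counted.

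The deposited signal intensity of each probe is on a linear scale, per the file headers and the values, with array medians from 139.5 to 186.3. The deposited detection p-value of each probe compares it with negative controls, as the values show. The submitters' processing notes name lumi and limma, with no version or role. The handling of background and the summary of beads are not given in the sources used here. A deposited table described as normalized and the series' value table held the same intensity values as the raw table (567876 of 567876 values equal in each), so neither was a separate alternative. No genome build is given in the sources used here, and no coordinates are reported.

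Of 47323 probes, 30113 were paired with 1 gene symbol in the platform annotation supplied, 8 with several and 17202 with none. Symbols were checked by Entrez ID against a RefSeq gene table of assembly GRCh38.p14, where 30074 matched and 0 were updated. Unnamed probes were tested separately, and the ERFE gene itself was not analysed here.

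Signals were background-corrected and normalized with neqc of limma 3.58.1 (R 4.3.3, statmod 1.5.0), with negative controls inferred from the detection p-values, an offset of 16 and quantile normalization. Probes with a detection p under 0.05 on at least 4 of 12 arrays were kept (18646 probes, of which 14152 had 1 symbol and 4494 no symbol). Each gene was represented by its probe with the highest mean, which left 10891 genes, 2679 of them with more than 1 such probe. A linear model with the 3 groups was fitted to all 12 arrays with lmFit and eBayes (9 residual and 3.56 prior degrees of freedom), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All p-values of genes and lists in the text are two-sided and come from limma. A gene with no detection on any array of 1 group has only a bound there, given as at least N-fold from the lowest detected signal of each array.

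Of 31 gene lists fixed beforehand, 30 had at least 3 measured members and were tested with camera (preset correlation 0.01), with an estimated correlation and with fry. Those named in the text are the BMP/SMAD1/5 targets, BMP and hepcidin pathway components, TGF-beta/activin targets, iron handling, hepatocyte transcription factors, NF-kB targets, acute phase genes, interferon-stimulated genes, NRF2 targets, immediate early genes and reference genes, and markers of stellate cells, macrophages and endothelium. Also named are the extracellular matrix genes and the cytochrome P450 and conjugation enzymes. Benjamini-Hochberg adjustment ran over the 30 lists of a comparison. The groups, tests, lists, alternatives and the naming rule were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls among called genes without overlap between arrays, all measured BMP targets, up to 4 members with the smallest p of each list that passed or held a called gene, and the 5 genes with the smallest p where fewer than 5 were called.

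The pipeline was tested on simulated data. In the simulated comparison of human ERFE with untreated cells over 11982 genes, 59 of 91 genes changed 2-fold were called (64.8%), 32 of 97 changed 1.5-fold (33.0%) and 7 of 11794 unchanged ones. In the simulated comparison of mouse ERFE with untreated cells, with no change put in, 0 of 11982 were called, and between human and mouse ERFE 57 (62.6%), 25 (25.8%) and 2 were. The 1 shifted list passed and 0 of 19 unchanged lists did. The simulated noise was independent between genes, whereas members of a real list can vary together (estimated correlation 0.51 for the interferon-stimulated genes). These counts therefore do not show how often unchanged genes or lists pass under such correlation. Arrays have no depth, and their number limits the precision.

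Alternatives were other normalizations, offsets, probe filters and probe rules, other models of the spread, fits of only the groups compared, the replicate number, title letter and title number as blocks, stricter thresholds, other list tests, and each array left out in turn. Settings that account for leukocyte transcripts were added after the data were seen. For comparisons sharing the untreated arrays, 1000 simulations of unchanged groups and all splits of these arrays were used, and 100 further simulations for the overlap of called genes, added after the data were seen and made by rotating the residuals, with 6 residual degrees of freedom.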

Results

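Gene expression was measured in Huh7 cells, an established human hepatoma line that makes hepcidin, after 24 h with recombinant erythroferrone (ERFE) at 10 µg/ml or without it. ERFE is a hormone of red cell precursors known to bind bone morphogenetic proteins (BMPs) and to lower hepcidin, the peptide that limits iron release into blood. Of the 12 Illumina HT-12 v4 arrays, 4 held untreated cells, 4 held cells given the human protein and 4 held cells given the mouse protein. The labels and the known action of ERFE pose 3 questions: what each protein changes, whether BMP target genes and hepcidin are among these changes, and whether the proteins of the 2 species differ. The arrays detected between 34.5% and 39.1% of their 47323 probes, and 10891 named genes could be tested. The 95th percentile of the raw signal was 11.7 to 15.4 times the median signal of the array, and the precision is limited by the number of arrays. No group given a vehicle or a control protein is among the 12 samples. A change against untreated cells therefore cannot be told apart from an effect of adding a protein preparation. Nothing states that the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

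In cells given human ERFE, HAMP, the gene of hepcidin, fell by 1.85 on the log2 scale. Its signal was 5.17 ± 0.26 (SD, n = 4) against 7.02 ± 0.31 in untreated cells, and it was detected on 1 of 4 treated arrays and on 4 of 4 untreated ones, with adjusted p = 0.000722. Because the probe lay near background on treated arrays, the size of the fall depends on the background step, with -0.68 without background correction and -1.23 with an offset of 50, both passing. The inhibitors of differentiation ID3, ID1 and ID2, which are direct targets of BMP signalling, fell by 1.01 ± 0.11 (SE), 0.75 ± 0.09 and 0.70 ± 0.11. SMAD6, an inhibitory SMAD that is induced by the same pathway, fell by 0.97 ± 0.11 (-0.55 without background correction). The adjusted p-values were 0.0026 for ID3, 0.00258 for SMAD6, 0.00416 for ID1 and 0.0166 for ID2, a second ID2 probe gave -0.74, and a second, dim ID1 probe gave -0.72 and did not pass (adjusted p = 0.087). SMAD7, the other inhibitory SMAD measured, had a log2 fold change of -0.56 that did not pass over all genes (adjusted p = 0.0864). BAMBI, a decoy receptor of the pathway, had -0.15, and the homeobox gene MSX1 and the repressor HEY1 had -0.38 and -0.15. Thus 5 of the 9 measured BMP/SMAD1/5 targets fell over all genes tested, and 6 adjusted over the list alone. With the number of the title code as a block, HAMP alone of these 5 passed, ID3, SMAD6 and ID1 having -0.90, -0.87 and -0.63 with adjusted p of 0.0609 to 0.0612 and ID2 -0.69 with adjusted p = 0.151, while the list passed (-0.72, adjusted p = 1.16e-12). The list as a whole fell by a mean of 0.72 (camera, adjusted p = 3.87e-19, and adjusted p = 0.000139 with an estimated correlation).

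**Figure D1:**
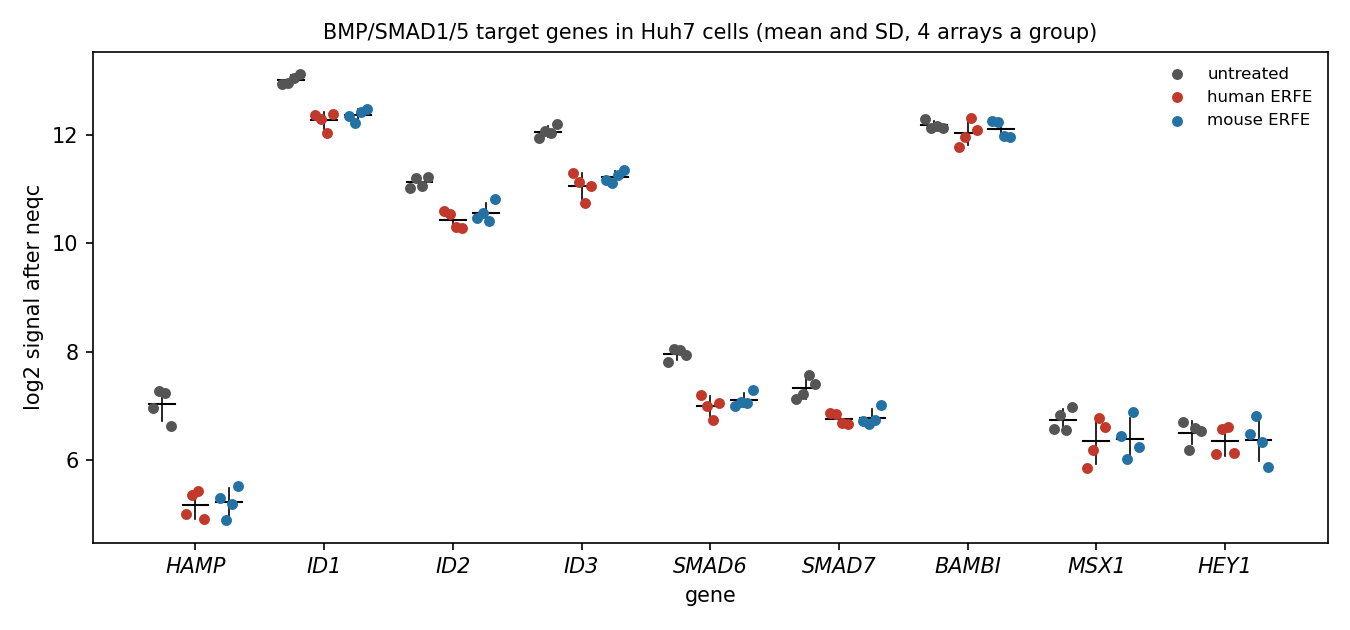
Signals (log2, after background correction and quantile normalization) of the 9 measured BMP/SMAD1/5 target genes, where each point is 1 of the 4 arrays of a group, the horizontal line is the group mean and the vertical line the SD. HAMP lay at 7.02 in untreated cells, 5.17 with human ERFE and 5.22 with mouse ERFE, while the group means of BAMBI lay between 12.04 and 12.19.

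Beyond the BMP list, TBX2, a T-box transcription factor, fell with human ERFE (-1.20 ± 0.15, adjusted p = 0.00365), as did the long noncoding RNA UCA1 (-1.11, adjusted p = 0.00638). PFKFB3, which sets the level of a main activator of glycolysis, fell by 0.83, SLC29A3, a nucleoside transporter of lysosomes, by 0.69, and MTURN by 0.64. A second PFKFB3 probe had -0.32 and did not pass (adjusted p = 0.763), and with the mean of its probes PFKFB3 had -0.57 and did not pass (adjusted p = 0.065). Without background correction TBX2 had -0.49 and UCA1 -0.58, both passing, while MTURN had -0.27 and did not pass (adjusted p = 0.0592). Among called genes the largest rise was that of CXCL1, a chemokine that attracts neutrophils, from 7.44 ± 0.09 to 8.58 ± 0.14 (SD, n = 4), a 2.20-fold change (log2 1.14 ± 0.10, adjusted p = 0.00049). The related chemokine CXCL6 rose by 0.67 and NFKBIZ, an atypical regulator of NF-kB, by 0.62, with adjusted p = 0.00543 and 0.0247. The second CXCL6 probe had 0.42 and did not pass (adjusted p = 0.595). LFNG, a glycosyltransferase that modifies Notch, rose by 0.66, the poly(A) polymerase gene TENT5C by 0.59, the nuclear receptor NR0B2 (SHP) by 0.57 and TCIM by 0.51. Other LFNG probes had 0.50 and -0.05 without passing, and with the mean of its probes LFNG had 0.37 (adjusted p = 0.424). Without background correction CXCL1 had 0.75, CXCL6 0.44, NFKBIZ 0.41, NR0B2 0.37 and FAM174B 0.35, all passing, and LINC01451 (0.26) and GPATCH1 did not pass (adjusted p = 0.109 and 0.125). LINC01451 and FAM174B rose by 0.70 and 0.65. GPATCH1 was detected on 3 of 4 treated and on 0 of 4 untreated arrays, so its signal is given only as at least 1.04-fold higher (adjusted p = 0.0148).

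CXCL1 was the only one of 13 measured NF-kB targets that changed with human ERFE over all genes, while NFKBIA had -0.31, CXCL2 0.47 and IL32 0.27, none passing over all genes and NFKBIA alone of these adjusted over the list alone, and the list did not pass (mean 0.09, adjusted p = 0.278). Of 10 hepatocyte transcription factors 1 changed, NR0B2, beside values of 0.37 for ONECUT1, 0.22 for FOXA2 and -0.14 for CEBPA that did not pass, and the list had a mean of 0.11 (adjusted p = 0.278). The 15 interferon-stimulated genes had a mean of -0.38 with 0 members passing over all genes or adjusted over the list alone. IRF7 had -0.56, IFI44 -0.48, IFI6 -0.33 and IRF9 -0.31. The list passed with the preset correlation (adjusted p = 0.0097) and not with an estimated one (adjusted p = 0.571 with an estimated correlation). Transcripts of MHC class II genes, which mark antigen-presenting cells, were high on 3 of 4 untreated, 2 of 4 human ERFE and 1 of 4 mouse ERFE arrays, and the interferon list was high on the same 6 arrays. With the MHC class II level as a covariate, chosen after the data were seen, the mean of the interferon list was -0.09. The 11 NRF2 targets, genes of the oxidant response, had a mean of -0.17, with HMOX1 at -0.53, AKR1B10 at -0.60, SRXN1 at -0.21 and AKR1C2 at -0.19, and 0 members passed over all genes and 1, AKR1B10, adjusted over the list alone (adjusted p = 0.00718 for the list, and adjusted p = 0.198 with an estimated correlation). The 6 stellate cell and fibroblast markers had a mean of 0.24 (adjusted p = 0.0116, and adjusted p = 0.198 with an estimated correlation). Among them PDGFRA had 0.46 at the probe tested and 0.04 at a second probe of like brightness, COL1A2 had 0.26, PDGFRB was at least 1.13-fold higher with detection on 3 of 4 treated and 0 of 4 untreated arrays, and DCN had 0.17, all short of the threshold over all genes and over the list alone.

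Among the 10891 genes, limma called 12 higher and 15 lower with human ERFE at an adjusted p of 0.05, with 760 genes under an unadjusted p of 0.05 where 544.55 would be so by chance. The 4 treated arrays lay all above or all below the 4 untreated ones for 435 genes (3.99%, where chance gives 2.86%), all of the called genes among them. Of the 30 lists tested, 4 passed with the preset correlation, 1 with an estimated one (the BMP targets) and 1 with fry (8 with fry's test of change in either direction). With median centring of each array instead of quantile normalization, 1 gene was higher and 5 lower. With the title number as a block 2 were higher (CXCL1 and LFNG) and 3 lower (HAMP, UCA1 and PFKFB3). That block took the call from 15 of the 20 genes called and named, TBX2, SLC29A3, MTURN, CXCL6, NFKBIZ, TENT5C, NR0B2 and TCIM among them. The title number is uneven over the groups, with no untreated array under 2, no mouse ERFE array under 3 and no human ERFE array under 4. The block therefore also costs precision, and a lost call does not show that it explains the change. Leaving out 1 array gave 6, 3, 7 and 37 genes higher without untreated replicates 1 to 4, and 5, 4, 4 and 6 without human ERFE replicates 1 to 4. The number lower dropped to 8 without untreated replicate 2, 9 without human ERFE replicate 3 and 8 without human ERFE replicate 4. Of the 20 genes called and named here, 11 passed whichever array was left out, namely HAMP, ID1, ID3, SMAD6, TBX2, UCA1, PFKFB3, SLC29A3, CXCL1, CXCL6 and LFNG, and the other 9 lost the call without at least 1 array (adjusted p up to 0.18). With the 2 arrays titled mouse ERFE replicate 3 averaged, which changes the shared estimate of the spread, LINC01451, FAM174B and TENT5C lost the call (adjusted p = 0.0643, 0.0572 and 0.0643).

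**Figure D2:**
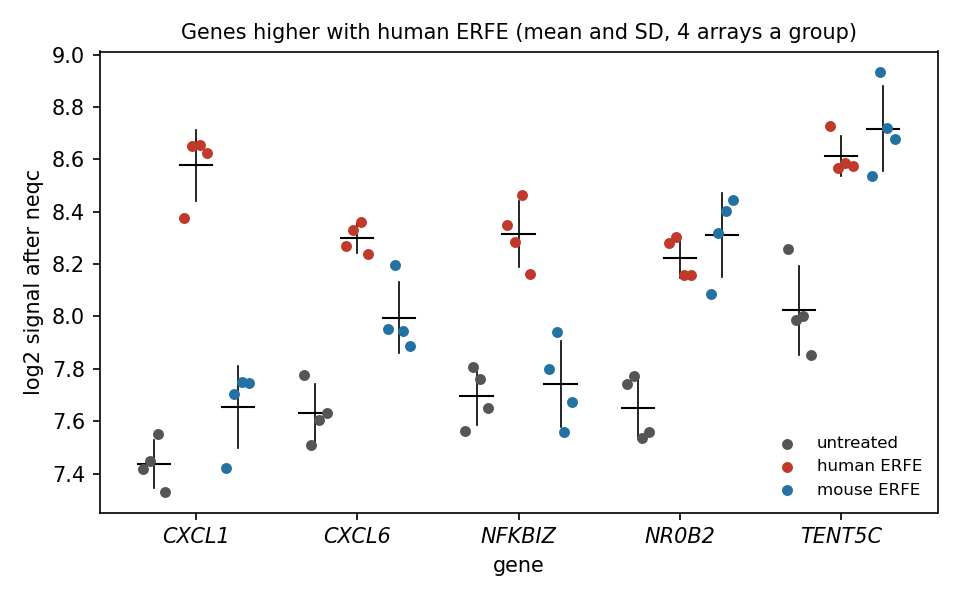
Signals (log2, after background correction and quantile normalization) of 5 genes that rose with human ERFE, per array, with the group mean (horizontal line) and SD (vertical line) over 4 arrays. For CXCL1 the 4 human ERFE arrays lay between 8.37 and 8.65 and the mouse ERFE arrays between 7.42 and 7.75, while NR0B2 and TENT5C rose with both proteins.

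The hepcidin gene and BMP target genes also fell with mouse ERFE. HAMP fell by 1.81 on the log2 scale, to 5.22 ± 0.26 (SD, n = 4), and was detected on 1 of 4 treated arrays (adjusted p = 0.00193), with -0.66 without background correction and -1.21 with an offset of 50, both passing. SMAD6 fell by 0.86, ID3 by 0.84 and ID1 by 0.66, with adjusted p = 0.00559, 0.0102 and 0.0126, while the second ID1 probe had -0.30 and did not pass (adjusted p = 0.446). ID2 had -0.56 at the probe tested (adjusted p = 0.0605), and its second probe had -0.66 and passed over all probes (adjusted p = 0.0285). SMAD7 had -0.54 (adjusted p = 0.0693), MSX1 -0.34, HEY1 -0.13 and BAMBI -0.07. Over all genes 4 of the 9 measured members fell, and 6 adjusted over the list alone. The list fell by a mean of 0.65 (camera, adjusted p = 4.11e-12, and adjusted p = 0.000901 with an estimated correlation).

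TBX2 fell by 1.26 with mouse ERFE (2.40-fold, adjusted p = 0.00559) and UCA1 by 0.94 (adjusted p = 0.0217). CDX2, a homeobox factor of the intestine, fell by 0.71, SH3TC1 by 0.70, and SLC29A3 and PFKFB3 by 0.69 each. The second PFKFB3 probe had -0.48 and did not pass (adjusted p = 0.283), and with the mean of their probes PFKFB3 had -0.58 and LFNG 0.57, just short of the threshold (adjusted p = 0.0577 and 0.0674). Without background correction TBX2 had -0.51, UCA1 -0.50, SMAD6 -0.50, CDX2 -0.42, LINC01451 0.29 and NR0B2 0.43, all passing, and CADM4 had 0.19 and did not pass (adjusted p = 0.121). Among called genes the largest rises were those of LINC01451 (0.76), TENT5C (0.69) and NR0B2 (0.66, adjusted p = 0.0126). The adhesion gene CADM4 rose by 0.62, LFNG by 0.58, and the trefoil factor genes TFF2 and TFF3, which encode secreted mucosal peptides, by 0.50 each (adjusted p = 0.0443 and 0.0122). TCIM rose by 0.49. NR0B2 was again the 1 hepatocyte transcription factor of 10 that changed, with PROX1 at 0.37, CEBPA at -0.29 and FOXA2 at 0.26 not passing, and the list had a mean of 0.10 (adjusted p = 0.573).

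With mouse ERFE the interferon list had a mean of -0.42 with 0 of 15 members passing, IRF7 at -0.62, OAS3 at -0.61, IRF9 at -0.60 and IFI6 at -0.33 (adjusted p = 0.0436 for the list, and adjusted p = 0.915 with an estimated correlation). MHC class II transcripts were high on 1 of the 4 mouse ERFE arrays against 3 of the 4 untreated ones, and with their level as a covariate the mean of this list was 0.01. The NRF2 targets had a mean of -0.21, with HMOX1 at -0.67, AKR1B10 at -0.48, SRXN1 at -0.38 and SLC7A11 at -0.31, and 2 of 11 members fell adjusted over the list alone (adjusted p = 0.0147 for the list, and adjusted p = 0.336 with an estimated correlation). Among 16 immediate early genes, 3 fell adjusted over the list alone and 0 over all genes. SPRY4 had -0.46 (-0.09 at a second, dim probe), MYC -0.45, DUSP1 -0.36 and DUSP5 -0.25, and the list had a mean of -0.09 and a median of -0.16 (adjusted p = 0.0491, and adjusted p = 0.509 with an estimated correlation). With the MHC class II level as a covariate the NRF2 list had a mean of -0.16 (adjusted p = 0.0807) and the immediate early list one of -0.08 (adjusted p = 0.143). In human ERFE cells 3 members of the immediate early list also fell adjusted over the list alone, and the list had a mean of -0.05 and did not pass (adjusted p = 0.21).

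In all, limma called 8 genes higher and 16 lower with mouse ERFE, with 1255 under an unadjusted p of 0.05 where 544.55 would be so by chance. Treated and untreated arrays did not overlap for 756 genes (6.94%, where chance gives 2.86%), all of the called genes among them. Of 30 lists 4 passed with the preset correlation, 1 with an estimated one (the BMP targets) and 3 with fry (12 with its test of change in either direction). Median centring gave 0 genes higher and 4 lower, and the title letter as a block gave 1 and 7. The submitters name 4 replicates per condition, which mouse ERFE reaches only with both arrays titled replicate 3 counted. The titles alone do not settle whether these are separate samples. With both averaged and counted as 1, 13 genes passed, 2 of them higher, and 7 of the 18 genes called and named here lost the call (LINC01451, TENT5C, NR0B2, LFNG, TFF2, TCIM and UCA1, adjusted p from 0.0503 to 0.129), as did the interferon, NRF2 and immediate early lists (adjusted p = 0.249, 0.0859 and 0.0859). Without untreated replicate 4, the only untreated array without high MHC class II transcripts, the counts rose from 8 to 75 higher and from 16 to 83 lower. The 3 untreated arrays left all had these transcripts high, against 1 mouse ERFE array. The added calls therefore cannot be told apart from that imbalance. Without untreated replicate 2 there were 2 higher and 8 lower, without untreated replicate 3 there were 1 and 7, and without mouse ERFE replicates 2 and 3-A4 there were 5 and 3 higher. Of 18 named calls 8 held whichever array was left out (HAMP, TBX2, SMAD6, ID3, CDX2, SH3TC1, SLC29A3 and TFF3), and 10 were lost without at least 1 array (adjusted p up to 0.158). With the number of the title code as a block, limma called 0 genes (1026 under an unadjusted p of 0.05). HAMP had a log2 fold change of -1.76 (adjusted p = 0.0883), against -1.81 without the block. As the title number is uneven over the groups, the block also costs precision.

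Between cells given the human and the mouse protein 1 gene passed, and species cannot be told apart from protein preparation in this design. CXCL1 was 1.89-fold higher with human than with mouse ERFE (8.58 ± 0.14 against 7.66 ± 0.16, SD, n = 4), a log2 difference of 0.92 with a 95% confidence interval of 0.71 to 1.13 and adjusted p = 0.00547. With mouse ERFE its log2 fold change against untreated cells was 0.22 (adjusted p = 0.422). The genes with the next smallest p, named as not passing, were NFKBIZ (0.57), the protein kinase gene PKN3 (0.57), the ectoenzyme gene CD38 (0.78), TRIM21 (0.60) and CEP68 (0.66), with adjusted p from 0.288 to 0.713. HAMP differed by -0.05, with an interval of -0.43 to 0.33, but with detection on 1 of 4 arrays in both groups this does not show that the proteins lowered it equally. The BMP targets differed by a mean of -0.08 (adjusted p = 0.187, and adjusted p = 0.448 with an estimated correlation), all 9 slightly lower with the human protein, and passed only with all probes as units (-0.11, adjusted p = 0.0302) or the mean of a gene's probes (-0.10, adjusted p = 0.0409). No list passed with camera or with fry in 1 direction, the smallest adjusted p of camera being 0.054 for the stellate cell and fibroblast markers (mean 0.25), followed by 0.071 for the NF-kB targets (0.18) and the acute phase genes (0.12), while the NF-kB list passed fry's test of change in either direction (adjusted p = 5.34e-08). That list includes CXCL1, and fry was not run without it, so this is no support beyond CXCL1. The 12 other members had a mean of 0.11 (camera with an estimated correlation, p = 0.167). Adjusted over the list alone, CXCL2 also passed among the NF-kB targets, CEBPD among the acute phase genes, PDGFRB and COL1A2 among the stellate cell markers and HJV among the pathway components, named after their values were seen, with CXCL2 and COL1A2 detected on 0 of 4 mouse ERFE arrays. Second probes of like brightness had -0.13 for HJV (0.53 at the probe tested) and 0.14 for COL1A2 (0.66 at the probe tested). Also over the list alone, PECAM1, the 1 endothelial marker measured, passed higher (0.37), as did 1 extracellular matrix gene. In the other direction, 1 member of the cytochrome P450 and conjugation enzymes passed lower. limma called 1 gene higher and 0 lower, with 536 under an unadjusted p of 0.05 where 544.55 would be so by chance, and arrays of the groups did not overlap for 264 genes (2.42%). CXCL1 passed whichever array was left out (adjusted p up to 0.0407). Its call was lost when only the 2 groups compared entered the fit (0.92, adjusted p = 0.0887) and with the title number as a block (0.90, adjusted p = 0.0514).

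Most of the genes called for one protein were called for the other. The 7 genes that rose with both were CADM4, LFNG, LINC01451, NR0B2, TCIM, TENT5C and TFF3, where independent lists would share 0.00881. The 13 that fell with both were HAMP, ID1, ID3, SMAD6, TBX2, UCA1, PFKFB3, SLC29A3, MTURN, CDX2, SH3TC1, CLRN3 and the calcium-binding protein gene S100P, where independent lists would share 0.022. These numbers leave out that both comparisons use the same untreated arrays. In 100 simulations of unchanged groups against shared arrays, limma's test called 0 genes in the same direction in both. Any gene was called in 6 simulations of the first comparison and 5 of the second, up to 44 and 2 genes, and 1 of the 100 reached the 27 called with human ERFE. With the untreated arrays split 2 and 2, so that none was shared, 0 genes were called higher and 0 to 4 lower in both over the 6 splits, HAMP in 5 of them, with 478 to 1327 genes under an unadjusted p of 0.05. The 31 genes called in either comparison all had the same sign in both, but they were chosen by those calls and the untreated arrays are shared, and among all genes unchanged simulated groups gave the same sign for 66.7%. CXCL1 was the only one of the 31 whose difference between the proteins passed. Passing with the human protein alone were CXCL1, CXCL6, FAM174B, GPATCH1 and NFKBIZ (higher) and ID2 and NUP62CL (lower), and with the mouse protein alone TFF2 (higher) and PKN3, TNFRSF1A and TOR4A (lower). S100P, CLRN3, NUP62CL, TNFRSF1A and TOR4A are named here as members of these counts, after their values were seen. Across the 10891 genes, which are not independent replicates, the log2 fold changes of the 2 comparisons had a Pearson r of 0.698. The comparisons share their untreated arrays, and simulated groups with no effect against the same arrays gave a mean r of 0.497 (0.192 to 0.723 in 1000 simulations). The covariance was 0.0252 against 0.0133 in the simulations, a difference of 0.0119, and r and covariance both lay within the range of the simulations (0.00478 to 0.0267 for the covariance). With these arrays split, r was 0.264 (0.161 to 0.324 over 6 splits).

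**Figure D3:**
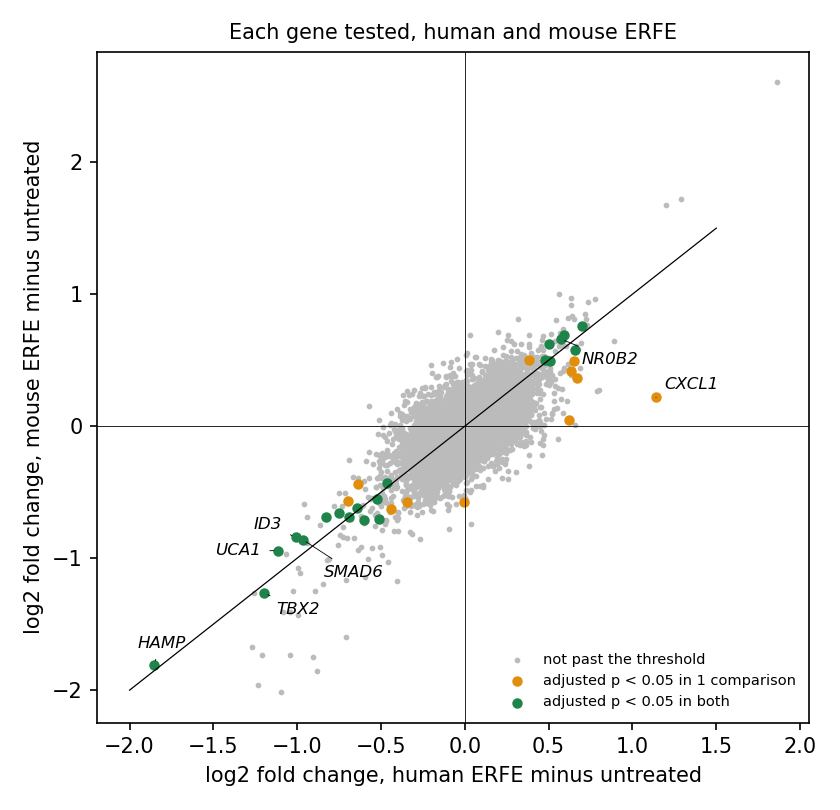
Log2 fold change of each of the 10891 genes with human ERFE (horizontal axis) and mouse ERFE (vertical axis) against untreated cells, where coloured points passed an adjusted p of 0.05 in 1 or in both comparisons, and the diagonal marks equal change. HAMP lies near it at -1.85 and -1.81, and CXCL1 lies apart at 1.14 and 0.22.

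Iron and BMP signalling genes outside the target list did not pass over all genes. Of 19 iron handling genes 0 changed with either protein over all genes or adjusted over the list alone, with list means of -0.03 (adjusted p = 0.528) and -0.06 (adjusted p = 0.573). The 12 measured BMP and hepcidin pathway components had 0 members passing (adjusted p = 0.877 and 0.88, with a mean and median just under 0 and a test direction upward), and so had the 14 TGF-beta/activin targets over all genes (adjusted p = 0.823 and 0.857). Adjusted over the list alone, THBS1 of the latter, which encodes thrombospondin, rose with both proteins (0.47 and 0.40), and SPHK1 and FSTL3 fell with mouse ERFE (-0.58 and -0.52), and fry's test of change in either direction gave adjusted p = 0.34 and 0.00197 for this list. The reference genes had adjusted p = 0.877 and 0.963. The macrophage markers had means of -0.23 and -0.22 (adjusted p = 0.348 and 0.857), of which CD14 was lower with both proteins adjusted over the list alone (-0.30 and -0.31). The arrays with high MHC class II transcripts were 3 untreated, 2 human ERFE and 1 mouse ERFE array. Lower macrophage markers with ERFE cannot be told apart from that unequal spread. The 1 endothelial marker measured, PECAM1, had 0.05 and -0.32 and did not pass over all genes. The members of these lists were named after their values were seen.

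Transcripts of antigen-presenting cells set 6 arrays apart from the rest in every group. HLA-DRA, the alpha chain of an MHC class II molecule, lay between 9.52 and 11.03 on untreated replicates 1, 2 and 3, human ERFE replicates 1 and 3 and mouse ERFE replicate 1, and between 7.06 and 7.93 on the other 6. The 6 were separated from the rest by the detection of at least 6 of 12 probes for dendritic cell genes such as CD1A, FCER1A and CCL22, with 7 to 9 detected against 2 to 3. The mean of the interferon list was 6.73 to 7.20 on these 6 arrays and 5.94 to 6.16 on the others. The BMP targets were lower with ERFE within each kind of array, with means of -0.74 and -0.73 for human ERFE and -0.67 and -0.63 for mouse ERFE on the arrays with few and with many of these transcripts. In 3 of these 4 comparisons 1 side held 1 array, and limma called 0 single genes among either 6 arrays alone (416 and 708 under an unadjusted p of 0.05 for human ERFE, 459 and 933 for mouse ERFE). With the kind of array as a block, 6 genes were higher and 11 lower with human ERFE, and 2 higher and 13 lower with mouse ERFE.

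**Figure D4:**
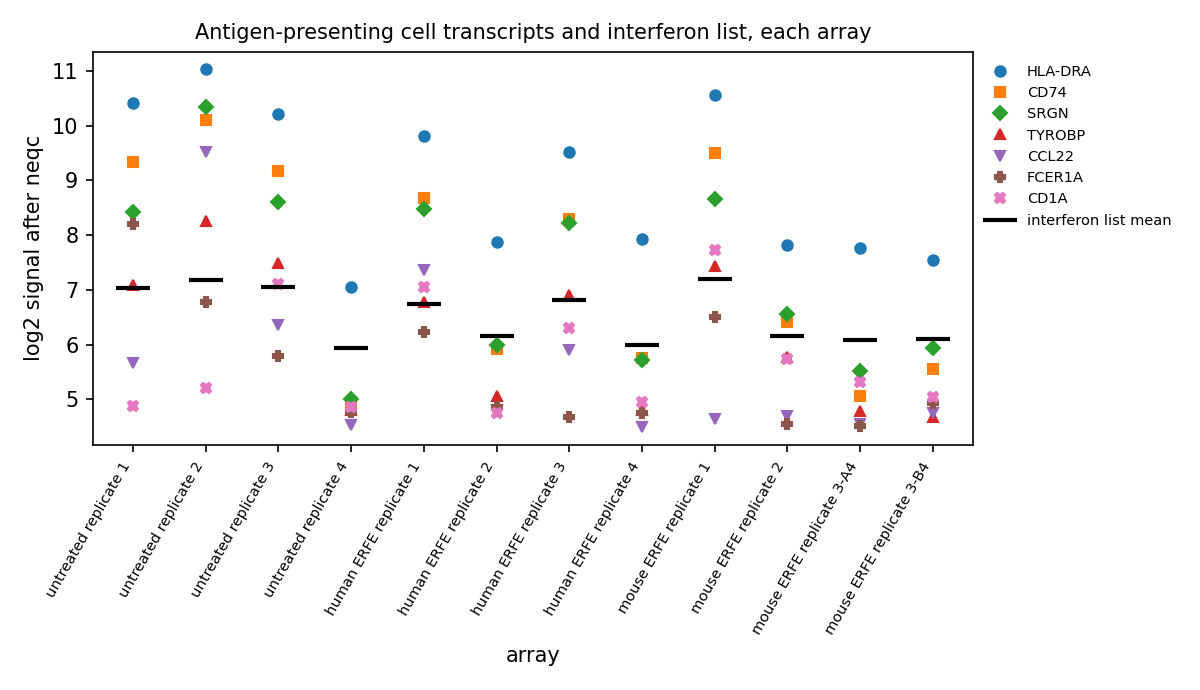
Signals (log2) of 7 genes of antigen-presenting cells and the mean of the 15 interferon-stimulated genes (black bars) on each of the 12 arrays, named by group and replicate. On the 6 arrays with high HLA-DRA, from 9.52 upward, the interferon list lay at 6.73 or higher, while untreated replicate 4 had the lowest HLA-DRA at 7.06.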

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

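Chosen only after the results were seen were the tests of the leukocyte transcripts and of the NF-kB list without CXCL1, and the settings that use the leukocyte transcripts.

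Single arrays stood apart within their group of 4 for 12 of 195 groups of values tested, where chance gives about 9.75. The value given is the gap to the nearest array divided by the range of the group. CXCL1 was lowest on human ERFE replicate 1 (8.37 against 8.63 to 8.65, gap 0.90) and on mouse ERFE replicate 1 (7.42 against 7.70 to 7.75, gap 0.863). On human ERFE replicate 1, TENT5C was highest (8.73, gap 0.88), TBX2 lowest (5.43 against 6.04 to 6.15, gap 0.856) and PKN3 lowest (6.31, gap 0.883). UCA1 and DUSP5 were highest on human ERFE replicate 2 (the other arrays at 6.46 to 6.55 for UCA1 and 11.22 to 11.24 for DUSP5, gaps 0.832 and 0.86). MTURN was highest on untreated replicate 3 (7.10, gap 0.8291), and CXCL2 lowest on mouse ERFE replicate 3-A4 (4.67, gap 0.841). The interferon list mean was lowest on untreated replicate 4 (5.94 against 7.04 to 7.18, gap 0.885) and highest on mouse ERFE replicate 1 (7.20 against 6.08 to 6.16, gap 0.93), where the MHC class II mean was also highest (7.92, gap 0.837).

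Among the 4494 probes without a gene name here, which no comparison of genes uses, 3 passed with mouse ERFE when all probes were tested together, with log2 fold changes of -0.88, 0.63 and -0.63 (adjusted p = 0.03, 0.0459 and 0.0285).

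Transcripts of antigen-presenting cells were high on 6 arrays, and leukocyte RNA in these arrays may be the source. Of 15 measured members of a second list of abundant leukocyte genes, 6 were at least 0.5 log2 higher, which met the bound set against this source (at most 4 in 10). That bound was set aside after the values were seen, because 8 of the 9 members below it were detected on fewer than all 6 arrays, while 4 of the 5 detected on all of them were higher (ITGB2 8.54 against 7.41, ARHGDIB 7.63 against 6.29, LCP1 9.64 against 9.12), so this source stays open. LAPTM5, CTSS and CYBB, abundant in such cells, were detected on 0 of these 6 arrays, but at signals near the floor this decides nothing. Support for this source is limited, because the 5 members were also detected on the other 6 arrays. In addition, 8 of the 15 are also in the first lists. Both kinds of array were present in 3 of 3 groups, which argues against an all-or-none effect of ERFE. The 6 arrays were 3 untreated, 2 human ERFE and 1 mouse ERFE array, so a partial lowering by ERFE stays open. The dendritic cell probes, of which a median of 6 more were detected, separated the 6 arrays. The MHC class II mean, without these probes, sets the same 6 apart (7.12 to 8.13 against 5.25 to 5.97). On that split, 7 to 9 of 12 dendritic cell probes were detected against 2 to 3. An interferon response of the Huh7 cells was not predicted to raise them. This argues against it as the only source of these transcripts, while such a response beside another source stays open.

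CXCL1 was 0.92 higher with human than with mouse ERFE on the log2 scale. With the MHC class II level as a covariate the difference was 0.93 (adjusted p = 0.00787), which argues against leukocyte RNA as its source. An NF-kB stimulus in the human ERFE preparation could raise CXCL1, but the 12 other NF-kB targets (mean 0.11, 7 of 12 higher) gave p = 0.167 with an estimated correlation in camera of limma, which decides nothing. Protein preparation and species cannot be told apart in this design, and a difference between the species' proteins stays open, untested.

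The interferon list was lower with both proteins, by means of -0.38 and -0.42. With the MHC class II level as a covariate these were -0.0855 and 0.0113, as an unequal spread over the groups of leukocyte RNA, or of an interferon response that raises MHC class II, would give. An effect of ERFE stays open. Within a kind of array the mean was under 0 in 1 of 4 comparisons (human ERFE 0.13 and -0.32, mouse ERFE 0.17 and 0.10), which met the bound set against it. That bound was set aside after the values were seen, because 3 of the 4 had 1 array on a side, and the 1 with more, human ERFE on arrays with leukocyte transcripts, gave the -0.32.

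The 8 arrays of each comparison were also split in other ways. For human ERFE against untreated, 1 of 35 splits of the 8 arrays, the real one, gave as many genes as the real 27, the highest other giving 1. That share is under 0.05, and 35 splits allow no smaller one. It excludes chance only if the 8 arrays are exchangeable. Nothing states that the arrays of a group came from separate cultures, so this is not known. In 100 simulations of unchanged groups 1 called at least as many (44 genes). For mouse ERFE 2 of 35 did, the real split giving 24 and the highest other 42, so chance cannot be excluded. That other split sets untreated replicates 1, 2 and 3 and mouse ERFE replicate 1, the arrays rich in leukocyte transcripts, against the rest, and with these as a block 2 genes were higher and 13 lower with mouse ERFE. Between human and mouse ERFE 4 of 35 splits gave at least the real 1 gene, the highest other giving 7, so chance cannot be excluded for that count.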

How the results depend on the processing

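The settings that use leukocyte transcripts, the within-kind comparisons included, were tests chosen only after the data were seen. Of 2117 values of named genes under the other settings, 1854 stayed on their side of the threshold, 238 lost it, 25 gained it and 0 reversed. Most named genes were not called to begin with. Of 86 named values, 20 were called for human ERFE, 18 for mouse ERFE and 1 between the proteins. Only these could lose a call, so the share of calls lost was larger than 238 of 2117. The BMP target list passed for both proteins in every setting run, with means of -0.74 to -0.71 (human ERFE) and -0.67 to -0.63 (mouse ERFE) as arrays were left out. Except where stated, the cause of a change was not tested. The size of changes of dim genes such as HAMP depends on the background step (-0.68 and -0.66 without it, -1.23 and -1.21 with offset 50), and HAMP drops out under the strict detection filter. The authors' normalized table and the series matrix were not run separately because they equal the raw table.

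For human ERFE 12 genes were higher and 15 lower. Higher were 1 with median centring, 5 with all probes, 4 with only the groups compared, 4 with the title letter and 2 with the title number as a block, 3 at adjusted p under 0.01, 6 with the MHC class II covariate and 6 with leukocyte transcripts as a block. Lower were 5 with median centring, 9 with only the groups compared, 3 with the title number and 8 at adjusted p under 0.01. Leaving out 1 array gave 3 to 37 higher and 8 to 15 lower. Of the lists 4 passed, 2 with the strict filter, 1 with an estimated correlation, 1 with fry, 1 among arrays with few leukocyte transcripts and 1 to 5 without 1 array.

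For mouse ERFE 8 genes were higher and 16 lower. The counts higher and lower were 25 and 54 without background correction, 0 and 4 with median centring, 13 and 25 with offset 50, 22 and 55 with the strict filter, 19 and 46 with trend and robust, 21 and 42 with array weights, 1 and 7 with the title letter and 0 and 0 with the title number. Higher were also 3 with only the groups compared, 2 with both replicate 3 arrays averaged, 4 at 1.5-fold, 4 with the covariate and 2 with the leukocyte block, and at adjusted p under 0.01 they were 0 and 6. Leaving out 1 array gave 1 to 75 higher and 7 to 83 lower, the highest without untreated replicate 4. Of the lists 4 passed, 2 with median centring, mean probes, only the groups compared or few leukocyte transcripts, 1 with averaged replicate 3, the title number, an estimated correlation, the covariate, the leukocyte block or the arrays with leukocyte transcripts, and 1 to 4 without 1 array.

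Between the proteins 1 gene was higher, and 0 with only the groups compared (limma, 497 under an unadjusted p of 0.05) or with the title number (749). It was 1 whichever array was left out, and 0 genes were lower. Of the lists 0 passed, 4 with all probes, 3 with mean probes, 2 with the leukocyte block, 1 on arrays with leukocyte transcripts and 0 to 1 without 1 array. The BMP list differed by -0.08, and passed at -0.11 with all probes (adjusted p = 0.0302) and -0.10 with mean probes (adjusted p = 0.0409), with -0.10 to -0.06 without 1 array. With median centring the median difference of all genes between the proteins was 0.15, against 0.01. The r of the 2 effects was 0.698, 0.264 with split controls and 0.617 to 0.803 without 1 array.

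Among 6 arrays of one kind limma called 0 genes in each comparison, few samples being left (416 to 933 under an unadjusted p of 0.05 against untreated). The interferon list reversed to 0.13 for human ERFE with few leukocyte transcripts, and for mouse ERFE to 0.0113 with the covariate, 0.0516 with the block, 0.17 with few and 0.10 with leukocyte transcripts.

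The replicate number shared across groups did not pair the arrays: 2 of 12 pairs had deviations correlated over 0.1, and 3 of 12 arrays correlated best with their own number. With the replicate block 4 genes were higher and 9 lower with human ERFE, and 19 and 39 with mouse ERFE.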

Other observations

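The genes and the leukocyte tests in this part were chosen only after the results were seen.

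Several large differences that did not pass had a wide spread among untreated arrays. KRT18, a keratin of simple epithelia, had a signal of 6.21 ± 1.64 (SD, n = 4) in untreated cells, 8.07 ± 0.62 with human ERFE and 8.81 ± 0.19 with mouse ERFE. Its log2 fold changes of 1.86 and 2.61 did not pass in limma (adjusted p = 0.498 and 0.106). ALYREF, an mRNA export factor, went from 6.23 ± 1.04 to 7.43 ± 0.52 and 7.90 ± 0.13, and USP22, a deubiquitinase, from 6.38 ± 1.18 to 7.67 ± 0.44 and 8.10 ± 0.23, without passing (adjusted p from 0.113 to 0.533). These genes were chosen after their values were seen.

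Among lists of leukocyte genes, those of monocytes and macrophages had 7 to 13 of 19 probes detected on the 6 arrays rich in antigen-presenting transcripts and 3 to 5 on the rest, and pan-leukocyte genes 7 to 9 of 18 against 3 to 6. Lymphocyte genes showed no such split. T cell genes had 2 to 6 of 18 probes detected, B cell genes 0 to 3 of 11 and NK cell genes 0 to 2 of 14 over the 12 arrays. PTPRC, the common leukocyte antigen, lay between 4.65 and 5.16. CCL22 was 9.53 on untreated replicate 2 and 7.36 on human ERFE replicate 1 but 4.64 on mouse ERFE replicate 1, while CD1A was 7.73 on the last.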
